A study of Mus musculus with 6 samples.

How the data were processed

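Bulk RNA sequencing of polyadenylated RNA was available for 6 mouse liver tumours, 3 from LysM-Cre control mice (Cre_PD1) and 3 from mice with a myeloid-specific Trem2 knockout (MKO_PD1). RNA was extracted with TRIzol and cleaned on columns, and libraries were built at a sequencing company. Per the labels, the submitters aligned the reads with STAR 2.7.10a to the mouse build mm10 and counted them per gene with featureCounts 2.0.3 of the Subread package.

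The deposited table holds 1 value per gene and library and is named as TPM, the scale assumed before the data were examined, but its values are a length-normalised read signal that the authors did not scale to a fixed total. The deposited column sums ranged from 70363 to 105281, and all 6 columns shared 1 constant of 8.03. Each value multiplied by the exon length of the gene in GENCODE mouse release M21 and divided by that constant gave a whole read number, within 0.001 reads in all 6 libraries, for 29374 of the 29860 genes (98.4%) with a length and a value above 0. The table listed 55291 genes, of which 53292 had a length and 24487 were at 0 in every library. Genes not recovered as whole reads, Dmbt1 among those named, kept their deposited value. How the submitters made the values is not stated beyond these tools.

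Each library was rescaled to a total of 1000000, which makes the values TPM, and analysed as log2(TPM + 1), with a pseudocount of 1. Genes with at least 1 TPM in at least 3 of the 6 libraries were tested, 16506 in all. The recovered reads per library ranged from 26750054 to 34268075, so 1 read on a gene of 1 kb of exon amounted to 0.0763 to 0.114 TPM. Reads carried no molecular identifiers, so the floors given for groups with 0 reads, 3 reads over a group, cover counting error only.

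The 2 groups were compared with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, no covariate and no block), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 differences are MKO_PD1 minus Cre_PD1 and folds given beside them come from the same fit with its pseudocount. Groups of 3 and 3 allow no exact two-sided permutation p below 0.1. The exact permutation test was set before the data were examined for the log2 level of Trem2. It was also applied to the ratios of Trem2 to macrophage genes, which were not part of that plan. Groups are said to be separate where the lowest value of one lies above the highest of the other, which chance gives for 10% of genes at this size.

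There were 38 gene lists fixed before the data were examined, together holding 549 genes of which 494 were tested, and Trem2 was in none. The 36 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. The skeletal muscle and pancreas acinar lists had too few members. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance without reference to other genes, were the other set tests. The size of these lists is given as the median log2 difference minus that of all tested genes, since the all-gene median moves with the scaling. Lists added later are given as plain median log2 differences, without that subtraction, and are not on the same scale. Members past the threshold were counted over all genes tested and adjusted over the list alone.

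The genes to name were set by rule before the data were examined. The rule takes Trem2 and, since fewer than 10 genes passed, the 10 higher and 10 lower genes of smallest unadjusted p, leaving out predicted genes, immunoglobulin and T cell receptor segments and pseudogenes, and then up to 4 members of each list by smallest p. The acute phase, mast cell and basophil, eosinophil, pericentral hepatocyte, periportal hepatocyte, liver-resident non-parenchymal, recruited tumour macrophage and platelet lists and the genes around Trem2 were chosen after the results were seen.

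Alternatives set before the data were examined changed the pseudocount (0.1 and 0.5), the filter (none, or 5 TPM), the scaling (median-of-ratios factors, quantile normalization, or removal of the hepatocyte list before scaling), the trend, the robust option, sample quality weights, a block on the replicate number, a threshold of 0.1 and each library in turn. Alternatives added after seeing the data were the values as deposited, limma voom on the recovered reads with median-of-ratios library sizes, genes with at least 60 recovered reads, the hepatocyte list mean as a covariate, and the fit without MKO_PD1 replicates 1 and 3. The procedure was tested on simulated counts of 14711 genes at this group size with a dispersion of 0.05. It recovered 100% of 4-fold and 51% of 2-fold changes, 4.24% of its calls were false, and none of 37 random lists was called. The simulated genes were drawn independently of each other, and the simulated libraries did not differ in tissue content. These rates need not hold for lists of correlated genes or for the real libraries. Nothing was left out of the table's 6 value columns. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and jsonlite 2.0.0 in R.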

Results

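The series holds polyadenylated RNA from 6 mouse liver tumours, each sequenced as 1 bulk library, in 2 groups of 3. All came from RIL-175/PD-1R tumours. RIL-175 is a mouse liver cancer cell line, and the labels do not say what PD-1R stands for. The Cre_PD1 tumours grew in LysM-Cre mice, whose Cre recombinase is active in macrophages, monocytes and neutrophils, and the MKO_PD1 tumours grew in mice lacking Trem2 in those cells. The mice had received anti-PD-1, an antibody against an inhibitory receptor of T cells, and the design text counts 3 mice of each genotype. The comparison asks what the loss of Trem2, a lipid-sensing receptor of macrophages, from myeloid cells changes in tumours under anti-PD-1. No tumour without anti-PD-1 is included and no label ties a library to a batch. The libraries held 30984030, 34268075 and 26750054 recovered reads in Cre_PD1 replicates 1, 2 and 3 and 32851866, 29496623 and 29237033 in MKO_PD1 replicates 1, 2 and 3. Levels are in TPM as mean ± SD of 3 libraries per group.

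As lists tested with a preset correlation, hepatocyte genes, Kupffer cell genes, neutrophil genes, macrophage genes and endothelial genes were higher, relative to all other genes, in tumours of MKO_PD1 than in tumours of Cre_PD1. Cell cycle genes, hypoxia and glycolysis genes and keratin and progenitor genes of liver tumours were lower. None of these lists was called with an estimated correlation or with fry. The urea cycle gene Cps1 was at 149 ± 92.7 TPM in Cre_PD1 and 638 ± 336 TPM in MKO_PD1. The lipid uptake receptor gene Cd36 was at 17.0 ± 3.63 and 57.8 ± 12.4 TPM and the keratin gene Krt19 at 3202 ± 1149 and 768 ± 513 TPM. Single genes, with 2 exceptions of few reads, did not pass the correction over all genes. The genes of T cells, cytotoxic cells and interferon responses spread more between the MKO_PD1 tumours than between the groups.

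Trem2 (ENSMUSG00000023992.14, chromosome 17, 48346401 to 48354147 on the plus strand of GRCm38, the assembly also named mm10) was at 14.0 ± 3.09 TPM in Cre_PD1 and 10.8 ± 6.21 TPM in MKO_PD1 (n = 3 each). The libraries held 530, 981 and 646 Trem2 reads in Cre_PD1 and 498, 888 and 356 in MKO_PD1. The log2 difference was -0.44 (SE 0.40), which did not pass the test (limma adjusted p = 0.432; exact permutation p = 0.4, two-sided). The median difference of all genes was -0.42 in the same fit. Without MKO_PD1 replicate 2 the Trem2 difference was -0.84 (limma adjusted p = 0.0450, in a range of 0.00347 to 1.0 over all alternatives). In that fit the median of all genes was -0.66 and 7314 of 15940 genes passed, so the fall was largely shared with other genes. Median-of-ratios scaling turned the Trem2 difference to 0.018. The pan-macrophage list was called higher in MKO_PD1 with the preset correlation but not with an estimated one (camera adjusted p = 0.668). Its mean overlapped between the groups, from 5.31 to 5.59 in Cre_PD1 and from 5.26 to 6.59 in MKO_PD1. Against the mean of 14 pan-macrophage genes the log2 level of Trem2 was -1.64 ± 0.22 in Cre_PD1 and -2.50 ± 0.34 in MKO_PD1, a ratio of 0.550 between the groups. The groups were separate for this ratio and for Trem2 against Csf1r (difference -1.18), Cd68 (-1.0), Adgre1 (-1.48), Tyrobp (-1.11), Lyz2 (-1.04) and the C1q genes (-0.82), each with an exact permutation p = 0.1, the smallest this design can give. These ratios were not planned beforehand and all share Trem2, so they are not independent of each other. Cx3cr1, a member of the pan-macrophage list, fell by more than Trem2 against the list mean (log2 differences of -1.68 and -0.86). Trem2 thus did not fall against every macrophage gene. A ratio within a library does not depend on the scaling. Reads were counted over all 4946 bases of Trem2 exons and the labels do not name the deleted part, so whole-gene reads do not measure the deletion itself.

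**Figure D1:**
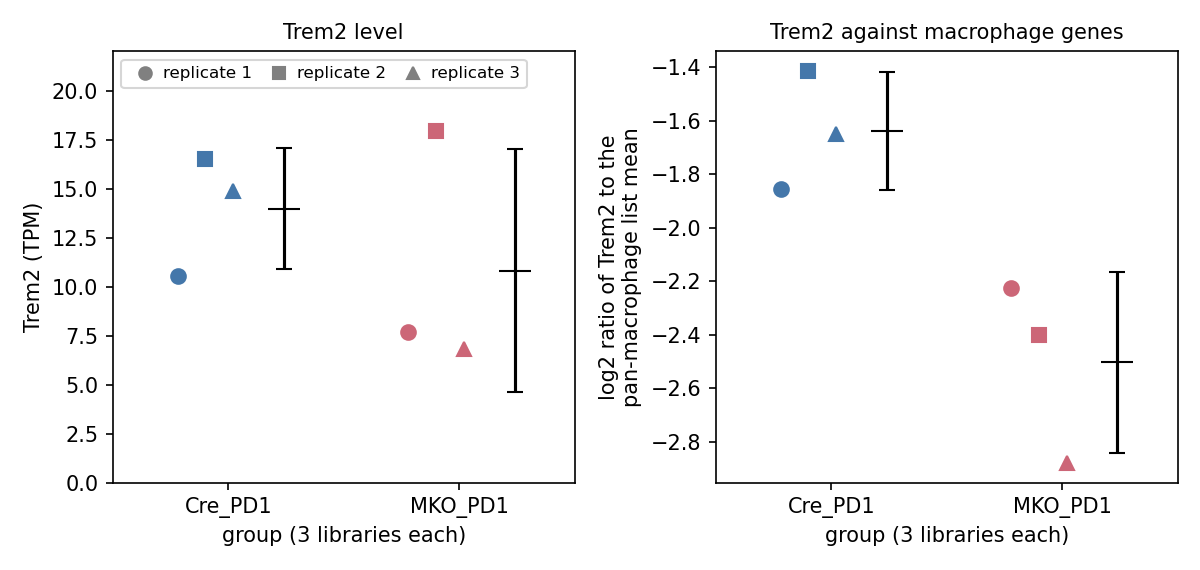
Trem2 level in TPM (left) and log2 ratio of Trem2 to the mean of the pan-macrophage list (right) in each library; symbols mark replicates and bars the mean ± SD of 3 libraries. The levels overlap, from 6.81 to 18.0 TPM in MKO_PD1 and from 10.5 to 16.5 TPM in Cre_PD1, whereas every ratio in MKO_PD1, at most -2.23, lies below every ratio in Cre_PD1, at least -1.86.

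The libraries differed in hepatocyte transcripts. The 24 hepatocyte list genes took 2.09, 4.23 and 4.68% of TPM in Cre_PD1 replicates 1, 2 and 3 and 20.1, 5.04 and 14.0% in MKO_PD1 replicates 1, 2 and 3 (3.67 ± 1.38 against 13.1 ± 7.60%). Mitochondrially encoded genes took 3.48 ± 0.764% in Cre_PD1 and 5.86 ± 0.935% in MKO_PD1. The predicted RNA gene Gm23935, chosen after its values were seen, took 2.14 ± 0.260 and 1.33 ± 0.241%. Pearson correlations between libraries, across genes, which are not independent replicates, ranged from 0.787 to 0.977. The first principal component held 71.9% of the variance. It placed MKO_PD1 replicates 1 and 3 at 124 and 44.8, MKO_PD1 replicate 2 at -22.1 and Cre_PD1 replicates 1 to 3 at -69.8, -32.4 and -44.7.

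Of 16506 genes tested, 2 passed the adjusted threshold in limma, 1 lower and 1 higher in MKO_PD1, and both rest on few reads. Reads on the microRNA gene Mir7655 (ENSMUSG00000099050.1, chromosome 2, 18057846 to 18057903, 58 bases) numbered 6, 5 and 5 in Cre_PD1. Each MKO_PD1 library had 0, at least 5.82-fold lower against a floor of 3 reads over the group (limma adjusted p = 0.0182). The libraries hold polyadenylated RNA, and whether such reads come from the microRNA or from an overlapping transcript was not tested. The same holds for the microRNA genes named below. The predicted gene Gm17720, outside the rule for named genes (chromosome 8, 110082803 to 110102753, with 27 bases of exon), rose, from 0 reads in each Cre_PD1 library to 3, 2 and 2 reads in MKO_PD1, at least 2.09-fold higher (adjusted p = 0.0182). The next smallest adjusted p was 0.161. At an unadjusted p under 0.05 there were 4612 genes, 1398 higher and 3214 lower in MKO_PD1, where chance gives 825 for independent genes. The groups were separate for 1671 genes higher and 4765 genes lower in MKO_PD1, 39.0% of genes against 10% by chance. The median log2 difference of all genes was -0.42 on the TPM scale and 0.0056 after median-of-ratios scaling, so list differences are given relative to it. Without MKO_PD1 replicate 2, whose hepatocyte share was nearest to Cre_PD1, 7314 genes passed, 1256 higher and 6058 lower. Without each other library in turn, 0 or 1 passed.

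The 10 genes of smallest p among those higher in MKO_PD1 all failed the correction (limma adjusted p = 0.168 for each), although each was higher in 3 of 3 MKO_PD1 libraries than in any Cre_PD1 library. Saa3 (chromosome 7, 46711998 to 46715700), an acute phase protein gene of inflamed tissue, was at 20.7 ± 4.75 TPM in Cre_PD1 and 92.6 ± 23.7 TPM in MKO_PD1 (log2 difference 2.10, SE 0.31). Cd36 (chromosome 5, 17781690 to 17888801), a receptor for fatty acids and oxidised lipoproteins, had a log2 difference of 1.70 (SE 0.28). Lpl (chromosome 8, 68880491 to 68907448), encoding lipoprotein lipase, was at 8.61 ± 0.277 and 33.4 ± 10.4 TPM. Atp6v0d2 (chromosome 4, 19876841 to 19922605), a subunit of the vacuolar proton pump in macrophages and osteoclasts, was at 7.66 ± 2.05 and 28.5 ± 6.33 TPM. Wfdc17, a myeloid gene, was at 132 ± 49.7 and 417 ± 48.6 TPM. The drug-metabolising liver enzyme gene Cyp3a11 was at 32.5 ± 16.6 and 181 ± 55.1 TPM, and the mitochondrial transfer RNA gene mt-Tc at 235 ± 17.1 and 833 ± 154 TPM. Prss34, a basophil protease gene, had 1, 0 and 0 reads in Cre_PD1 and 24, 29 and 22 in MKO_PD1. The microRNA gene Mir1948 had 0, 0 and 1 reads against 5, 6 and 8. The tenth gene, Treml1, lies beside Trem2 and is described with its neighbours.

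The 10 genes of smallest p among those lower in MKO_PD1 separated the groups, and apart from Mir7655 they also failed the correction. Dmbt1, a secreted scavenger receptor gene of epithelia, was at 66.2 ± 24.4 TPM in Cre_PD1 and 4.98 ± 2.60 TPM in MKO_PD1 (log2 difference -3.50, SE 0.41, limma adjusted p = 0.161). Glod5 was at 338 ± 85.7 and 51.3 ± 26.9 TPM. Eya2, a transcriptional coactivator gene of development, was at 63.6 ± 12.9 and 11.3 ± 6.78 TPM. Hes1, a target of Notch signalling, was at 82.4 ± 10.6 and 29.4 ± 7.62 TPM. Ndp, which encodes a ligand of Frizzled-4, was at 7.80 ± 1.25 and 1.39 ± 0.602 TPM. Sptssb, a subunit gene of serine palmitoyltransferase, was at 3.42 ± 0.957 and 0.275 ± 0.0167 TPM. Spink4 was at 3.71 ± 0.834 and 0.436 ± 0.219 TPM. The microRNA genes Mir7671, with 10 reads in Cre_PD1, and Mir6909, with 8, had 0 reads in MKO_PD1, at least 3.69-fold and 2.74-fold lower. Adjusted p was 0.168 for these genes other than Dmbt1, and the log2 differences of all named here stayed negative under median-of-ratios scaling.

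Of the 36 gene lists tested, camera with the preset correlation called 22, 18 higher and 4 lower in MKO_PD1. With an estimated correlation it called 0, with 2 lists at an unadjusted p under 0.05, and fry called 0, with 3 lists at an unadjusted p under 0.05. No list member passed the threshold over all genes tested. The estimated correlations ran from 0.127 (oxidative phosphorylation) to 0.978 (cell cycle), far above the preset 0.01. Splits of the 6 libraries that mix the groups called from 10 to 23 lists with the preset correlation. The count of 22 therefore does not set the genotype split apart.

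Hepatocyte genes were higher in MKO_PD1 as a list. All 24 members, which encode plasma proteins, cytochromes P450 and enzymes of amino acid breakdown, were higher in MKO_PD1, and 15 separated the groups. Of all 16506 genes tested, 1671 were separate and higher. Adjusted over the list alone, 20 passed, against 0 adjusted over all genes. The list median lay 2.19 log2 units above that of all genes (camera adjusted p = 1.78e-17; adjusted p = 0.668 with an estimated correlation). Tat, the first enzyme of tyrosine breakdown, was at 120 ± 91.0 TPM in Cre_PD1 and 468 ± 84.9 TPM in MKO_PD1. Ass1, of the urea cycle, was at 213 ± 127 and 898 ± 431 TPM. Cholesterol and fatty acid synthesis genes were higher by 1.14 (19 of 21 members above 0; camera adjusted p = 1.30e-07; adjusted p = 0.668 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. The elongase gene Elovl6 was at 23.4 ± 6.38 and 49.0 ± 19.6 TPM. The desaturase gene Scd2 was at 558 ± 117 and 201 ± 137 TPM and Srebf2, the transcription factor of sterol synthesis, at 84.7 ± 16.6 and 48.8 ± 10.8 TPM. The list difference was 0.667 without MKO_PD1 replicate 1 and 1.76 without MKO_PD1 replicate 2. Wnt target genes were higher by 0.90 (camera adjusted p = 0.00152; adjusted p = 0.668 with an estimated correlation), and 5 of 12 passed adjusted over the list alone, 4 higher and 1 lower. The 4 higher were Glul, the glutamine synthetase of hepatocytes around the central vein, at 172 ± 53.9 and 454 ± 168 TPM, Tbx3 at 1.13 ± 0.464 and 5.15 ± 1.93 TPM, and the genes of 2 inhibitors of Wnt signalling. Of these Rnf43 was at 2.24 ± 0.611 and 6.99 ± 1.30 TPM and Notum at 4.94 ± 3.20 and 18.5 ± 6.72 TPM. The lower one was Ctnnb1, encoding beta-catenin. With the hepatocyte list mean as a covariate the cholesterol and Wnt target lists were not called, and the hepatocyte list lost its call by construction. That mean was higher in every MKO_PD1 library than in any Cre_PD1 library, so this fit separates group from hepatocyte share poorly. The Wnt target call also ended with limma voom on recovered reads, and the Wnt target and cholesterol calls without MKO_PD1 replicates 1 and 3.

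Kupffer cell genes, those of the resident macrophages of the liver, and pan-macrophage genes were called higher in MKO_PD1 with the preset correlation and neither with an estimated one. All 10 Kupffer cell genes were higher and 4 separated the groups, but 0 passed adjusted over the list alone. The list lay 1.64 above all genes (camera adjusted p = 1.23e-07; adjusted p = 0.641 with an estimated correlation) and 1.02 without MKO_PD1 replicate 1. The iron exporter gene Slc40a1 was at 27.0 ± 3.67 TPM in Cre_PD1 and 71.9 ± 28.5 TPM in MKO_PD1. Cd5l was at 186 ± 80.2 and 630 ± 402 TPM and the nuclear receptor gene Nr1h3 at 47.9 ± 15.6 and 96.5 ± 36.8 TPM. The Kupffer cell list mean followed the hepatocyte share, at 7.48 and 7.05 in MKO_PD1 replicates 1 and 3 and at 5.93 in replicate 2, inside the Cre_PD1 range of 5.07 to 5.93. Its call ended with the hepatocyte list mean as a covariate (-0.14) and without MKO_PD1 replicates 1 and 3. Pan-macrophage genes were higher by 0.99 (12 of 14 members above 0, 6 separate, 0 past the threshold adjusted over the list alone; camera adjusted p = 9.86e-05; adjusted p = 0.668 with an estimated correlation). Among them the surface marker gene Adgre1 was at 37.9 ± 7.28 and 74.3 ± 5.64 TPM and the receptor gene Csf1r at 86.6 ± 7.29 and 142 ± 31.8 TPM. Msr1 was at 21.9 ± 3.84 and 41.9 ± 19.8 TPM and Mertk at 20.8 ± 3.46 and 32.0 ± 4.80 TPM.

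The genes of lipid-handling macrophages that are known to accompany Trem2 were higher as a list by 0.92 (camera adjusted p = 0.000412; adjusted p = 0.668 with an estimated correlation), but its members went both ways. Of 20 members, 8 were separate and higher and 4 separate and lower. Adjusted over the list alone 3 passed, the lipid genes Cd36, Lpl and Fabp5, the last at 53 ± 15.1 TPM in Cre_PD1 and 164 ± 90.1 TPM in MKO_PD1. All 3 were highest in MKO_PD1 replicate 1, at 65.4, 41.6 and 268 TPM. That library had the largest hepatocyte share (20.1%) and a pan-macrophage list mean (5.26) below every Cre_PD1 library. Bulk RNA does not show which cells expressed these genes. Spp1, a secreted protein also made by tumour cells and bile duct cells, was at 10529 ± 655 and 3194 ± 2130 TPM. Inflammatory macrophage genes were higher by 0.81 (camera adjusted p = 0.000412; adjusted p = 0.668 with an estimated correlation), with 0 of 13 past the threshold adjusted over the list alone. The cytokine genes Il18 and Il1a were at 14.6 ± 3.73 and 35.2 ± 11.9 TPM and at 7.76 ± 2.57 and 15.8 ± 2.15 TPM. The inflammasome gene Nlrp3 was at 5.54 ± 0.337 and 10.7 ± 7.04 TPM and the costimulatory gene Cd86 at 14.9 ± 0.286 and 22.5 ± 10.1 TPM. Alternatively activated or suppressive myeloid genes were higher by 0.68 (camera adjusted p = 0.00238; adjusted p = 0.668 with an estimated correlation). Of 15 members, 2 passed adjusted over the list alone, Chil3 at 7.43 ± 4.84 and 48.8 ± 21.2 TPM and Arg1, which hepatocytes also express, at 512 ± 151 and 1354 ± 333 TPM. Folr2, of resident macrophages, was at 4.33 ± 2.25 and 10.5 ± 5.47 TPM, while the cytokine gene Tgfb1 was lower, at 149 ± 21.5 and 67.0 ± 36.1 TPM. This call ended without MKO_PD1 replicate 2 (0.31, limma camera adjusted p = 0.0550).

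Neutrophil genes were higher by 2.09 (13 of 14 members above 0, 6 separate; camera adjusted p = 2.69e-08; adjusted p = 0.668 with an estimated correlation). Adjusted over the list alone, 8 passed, among them genes of primary and secondary granules, which are transcribed in immature neutrophils, and 0 passed over all genes. The list means overlapped, with 3.63 in MKO_PD1 replicate 1 and 3.78 in Cre_PD1 replicate 2. Elane, encoding neutrophil elastase, was at 3.30 ± 1.91 TPM in Cre_PD1 and 17.6 ± 12.4 TPM in MKO_PD1, and Mpo, encoding myeloperoxidase, at 1.52 ± 0.450 and 8.37 ± 6.32 TPM. Ngp was at 7.48 ± 6.81 and 52.1 ± 47.6 TPM and Retnlg at 13 ± 7.09 and 52.6 ± 28.2 TPM. Monocyte genes were higher by 0.88 (camera adjusted p = 0.00229; adjusted p = 0.742 with an estimated correlation), and Chil3 alone of 11 passed adjusted over the list alone. Ly6c2 was at 4.35 ± 1.29 and 18.9 ± 16.9 TPM, but Plac8 was at 1215 ± 280 and 452 ± 299 TPM. Myeloid-recruiting chemokine genes were higher by 0.49 (camera adjusted p = 0.00213; adjusted p = 0.783 with an estimated correlation). Of 14 members, 4 passed adjusted over the list alone. Of these the neutrophil attractant gene Cxcl1 was at 16.2 ± 6.71 and 53.4 ± 6.05 TPM, Cxcl12 at 19.3 ± 10.1 and 68.1 ± 11.6 TPM and Ccl9 at 46.7 ± 13.9 and 136 ± 51.6 TPM. The granulocyte growth factor gene Csf3 was lower, at 2.11 ± 0.631 and 0.321 ± 0.279 TPM. The chemokine call ended without MKO_PD1 replicate 2 (0.22, limma camera adjusted p = 0.0658). It was 0.28 without Cre_PD1 replicate 1, 0.85 without Cre_PD1 replicate 2 and 1.05 without MKO_PD1 replicate 1. Dendritic cell genes were higher by 0.47 (camera adjusted p = 0.0470; adjusted p = 0.830 with an estimated correlation). Of 11 members, 1 passed adjusted over the list alone, Clec9a, of cross-presenting dendritic cells, at 3.02 ± 0.422 and 8.25 ± 1.04 TPM. Their transcription factor gene Batf3 was at 8.55 ± 1.12 and 12.6 ± 1.74 TPM and Itgax at 33.6 ± 7.32 and 20.4 ± 14.1 TPM. The call ended without any single Cre_PD1 library (limma camera adjusted p = 0.0543, 0.0976 and 0.0950 without replicates 1, 2 and 3), where the difference stayed at 0.46, 0.51 and 0.56, and without MKO_PD1 replicate 2 (0.18, adjusted p = 0.411). It also ended with both other pseudocounts, no filter, the filter at 5 TPM, sample quality weights and the replicate block.

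T cell genes varied more between MKO_PD1 tumours than between groups. The list mean on the log2 scale was 2.99, 3.37 and 3.63 in Cre_PD1 replicates 1, 2 and 3 and 2.51, 4.75 and 2.95 in MKO_PD1 replicates 1, 2 and 3, so that the highest and the lowest library both belonged to MKO_PD1. The T cell list lay 0.49 above all genes (camera adjusted p = 0.0405; adjusted p = 0.897 with an estimated correlation) and the cytotoxic effector list 0.53 above them (camera adjusted p = 0.0470; adjusted p = 0.897 with an estimated correlation). In both lists 0 members passed adjusted over the list alone and 0 separated the groups. Icos was at 5.59 ± 1.94 TPM in Cre_PD1 and 10.5 ± 9.56 TPM in MKO_PD1. The cytokine gene Ifng was at 4.17 ± 2.63 and 8.87 ± 10.8 TPM and Ccl5 at 117 ± 31.1 and 255 ± 274 TPM. Both calls ended without Cre_PD1 replicate 1 (limma camera adjusted p = 0.188 and 0.194), with a pseudocount of 0.1, with no filter and with sample quality weights. The cytotoxic effector call also ended with a pseudocount of 0.5, the filter at 5 TPM, median-of-ratios scaling, the hepatocyte list removed and no trend. Without MKO_PD1 replicate 2 both lists tested as lower (0.054 and -0.046; adjusted p = 0.496 and 0.584). Among checkpoint genes Tnfrsf9 was at 192 ± 24.7 and 127 ± 114 TPM and Havcr2 at 29.0 ± 0.559 and 23.3 ± 20.5 TPM. The exhaustion and checkpoint list (camera adjusted p = 0.330), the regulatory T cell list (0.898) and the NK cell list (0.688) were not called, with 0 members past the threshold adjusted over the list alone. Without MKO_PD1 replicate 1 the exhaustion list was called higher (0.60, limma camera adjusted p = 0.00880). With the hepatocyte covariate and without MKO_PD1 replicates 1 and 3 the exhaustion list was called higher too, as was the regulatory T cell list (limma camera adjusted p = 0.0335 and 0.00723 for the latter). B and plasma cell genes were higher by 0.81 (9 of 9 members above 0; camera adjusted p = 0.00116; adjusted p = 0.668 with an estimated correlation), or by 1.43 without Cre_PD1 replicate 3, with 0 past the threshold adjusted over the list alone. Their call ended with the hepatocyte list mean as a covariate. The antibody genes Jchain and Igkc were at 10.7 ± 2.63 and 23.4 ± 9.21 TPM and at 210 ± 61.5 and 390 ± 115 TPM.

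No list of interferon response or antigen presentation genes kept a call with each library left out in turn. The type I interferon response list lay 0.49 above all genes (camera adjusted p = 0.0294; adjusted p = 0.897 with an estimated correlation), with 0 of 20 past the threshold adjusted over the list alone. Its call ended without Cre_PD1 replicate 1 (0.27, limma camera adjusted p = 0.127) and without MKO_PD1 replicate 2 (0.34, adjusted p = 0.443), and with no filter, the filter at 5 TPM, sample quality weights and the replicate block. Cmpk2 was at 2.63 ± 0.924 TPM in Cre_PD1 and 5.86 ± 1.87 TPM in MKO_PD1 and Mx2 at 2.88 ± 0.667 and 4.83 ± 0.316 TPM, but Oasl1 was at 75.4 ± 38.0 and 34.1 ± 13.6 TPM. The interferon gamma response list was not called (camera adjusted p = 0.0806). It was called higher without Cre_PD1 replicate 3 (limma camera adjusted p = 0.0255), without MKO_PD1 replicate 1 (0.000111) and without MKO_PD1 replicate 3 (0.0191). The same holds with the filter at 5 TPM, the hepatocyte covariate and without MKO_PD1 replicates 1 and 3. Iigp1 was at 186 ± 74.5 and 320 ± 193 TPM and Ido1 at 280 ± 55.0 and 219 ± 231 TPM. The T cell-recruiting chemokine list (adjusted p = 0.204), the MHC class I presentation list (0.663) and the MHC class II presentation list (0.571) were not called by camera, with 0 members past the threshold adjusted over the list alone. All 3 were called higher without MKO_PD1 replicates 1 and 3, and the MHC class II list also with the hepatocyte covariate. Cathepsin S, encoded by Ctss, was at 826 ± 137 and 1274 ± 890 TPM.

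Cell cycle genes and hypoxia and glycolysis genes were lower in MKO_PD1. Of all 16506 genes tested, 4765 were separate and lower. All 24 cell cycle genes were lower and 14 separated the groups, although 0 passed adjusted over the list alone. The list lay -0.87 from all genes (camera adjusted p = 0.000148; adjusted p = 0.830 with an estimated correlation) and -0.47 without MKO_PD1 replicate 1. The mitotic genes Aurka and Cdc20 were at 56.6 ± 6.17 TPM in Cre_PD1 and 22.7 ± 14.8 TPM in MKO_PD1 and at 99.8 ± 13.1 and 38.3 ± 27.1 TPM. Ccnb2 was at 91.2 ± 13.9 and 36.1 ± 26.6 TPM and Bub1b at 49.4 ± 7.74 and 20.4 ± 13.9 TPM. All 20 hypoxia and glycolysis genes were lower and 16 separated the groups, with 0 past the threshold adjusted over the list alone, at -0.74 from all genes (camera adjusted p = 0.00116; adjusted p = 0.830 with an estimated correlation). Car9, the hypoxia-induced carbonic anhydrase gene, was at 54.2 ± 2.99 and 18.0 ± 12.1 TPM. The pyruvate kinase gene Pkm was at 2392 ± 404 and 918 ± 620 TPM and Ndrg1 at 293 ± 80.4 and 105 ± 59.2 TPM. All 11 liver tumour and progenitor genes were lower and 6 passed adjusted over the list alone, Krt19, Krt8, Krt18, Spp1, Sox9 and Cd44. The list lay at -0.91 from all genes (camera adjusted p = 0.0113; adjusted p = 0.830 with an estimated correlation) and -0.56 without MKO_PD1 replicate 1. Krt8 was at 3623 ± 1302 and 1223 ± 596 TPM and Krt18 at 2941 ± 900 and 1107 ± 461 TPM. Cell cycle levels ran against the hepatocyte share, with list means of 3.22 and 4.60 in MKO_PD1 replicates 1 and 3 (hepatocyte shares of 20.1 and 14.0%) and 5.46 in replicate 2 (5.04%), below the Cre_PD1 range of 5.57 to 5.83. With the hepatocyte list mean as a covariate the cell cycle and the hypoxia and glycolysis lists were not called, while the liver tumour and progenitor list stayed called lower. Apoptosis and p53 genes lay at -0.38 (15 of 17 members below 0, 0 past the threshold adjusted over the list alone; camera adjusted p = 0.0470; adjusted p = 0.897 with an estimated correlation). The p53 target gene Pmaip1 was at 176 ± 57.9 and 66.3 ± 37.2 TPM. That call ended without Cre_PD1 replicate 1 (limma camera adjusted p = 0.0713), without Cre_PD1 replicate 2 (0.0507) and without MKO_PD1 replicate 2 (0.0598). It also ended with both other pseudocounts, the filter at 5 TPM, median-of-ratios scaling, quantile normalization, no trend and sample quality weights. The same holds for genes of at least 60 reads, the hepatocyte covariate and the fit without MKO_PD1 replicates 1 and 3.

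**Figure D2:**
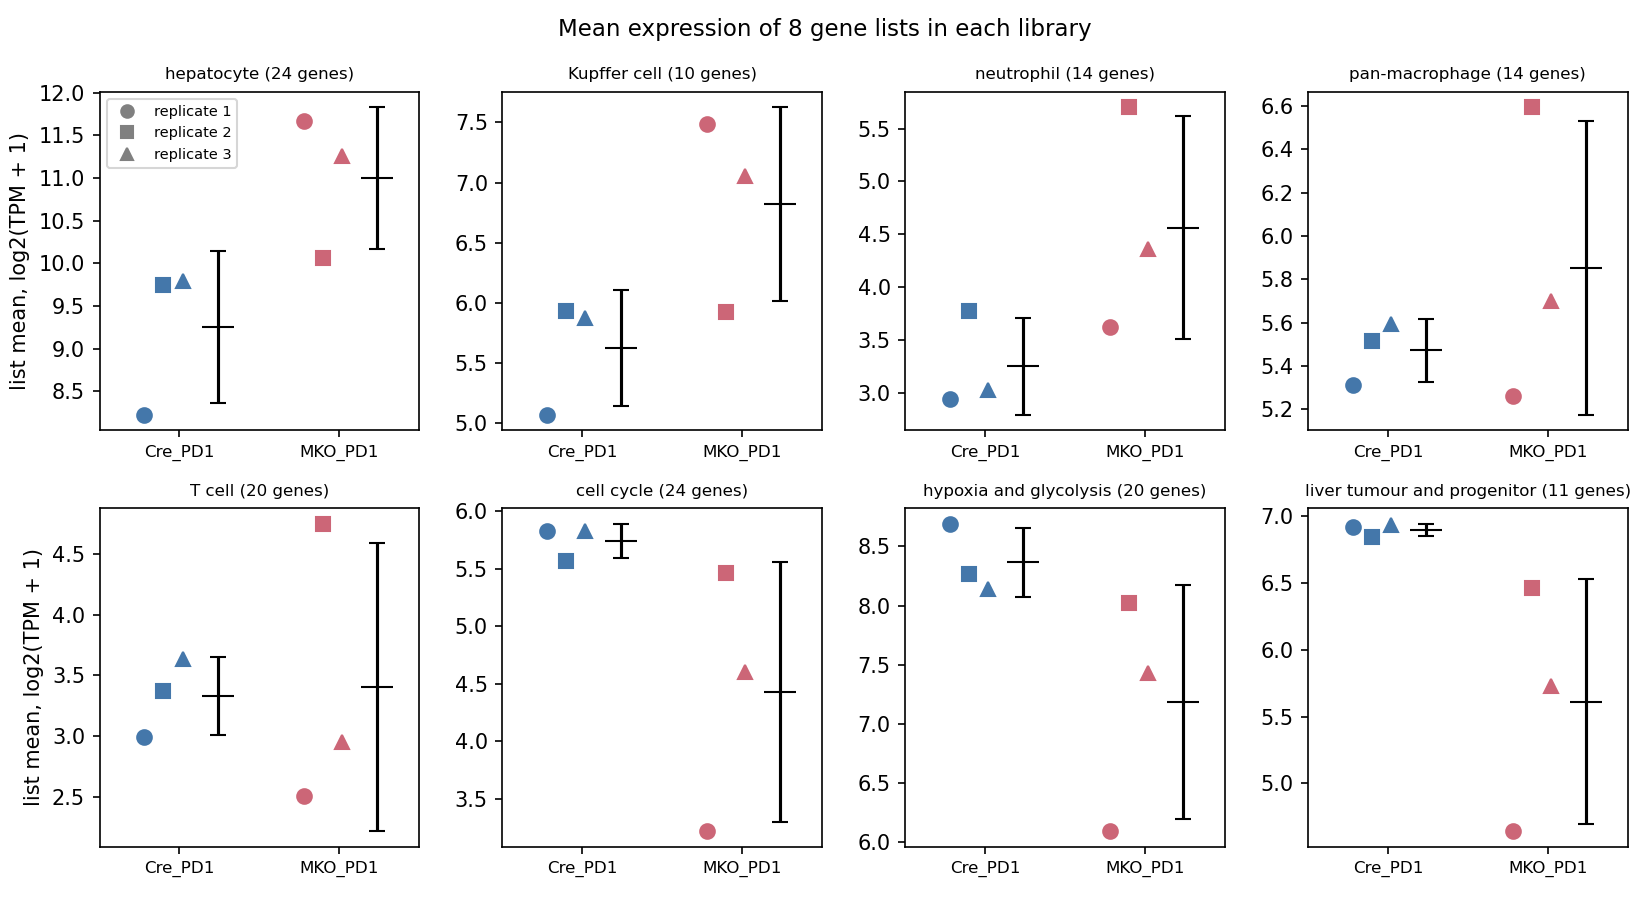
Mean log2(TPM + 1) of 8 gene lists in each library, with a vertical axis of its own in each panel that does not start at 0; symbols mark replicates and bars the mean ± SD of 3 libraries per group. The hepatocyte list is higher in every MKO_PD1 library (10.1 to 11.7) than in any Cre_PD1 library (8.22 to 9.79), the cell cycle list is lower in every MKO_PD1 library, and the T cell list overlaps.

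Endothelial genes were higher by 0.91 (14 of 16 members above 0, 7 separate, 0 past the threshold adjusted over the list alone; camera adjusted p = 1.15e-06; adjusted p = 0.641 with an estimated correlation). The list mean was 3.58 ± 0.18 in Cre_PD1 and 4.08 ± 0.089 in MKO_PD1 and, unlike the hepatocyte list, lay close together in the 3 MKO_PD1 libraries. Stab2 and Lyve1, of liver sinusoidal and lymphatic endothelium, were at 9.08 ± 1.30 TPM in Cre_PD1 and 24.6 ± 10.6 TPM in MKO_PD1 and at 12.5 ± 1.85 and 22.8 ± 4.58 TPM. The pan-endothelial cadherin gene Cdh5, also a member of the Kupffer cell list, was at 25.5 ± 0.641 and 40.4 ± 1.5 TPM and the angiopoietin receptor gene Tek at 3.58 ± 1.16 and 7.56 ± 2.56 TPM. Erythroid genes were higher by 0.57 (camera adjusted p = 0.0209; adjusted p = 0.668 with an estimated correlation), with 0 of 9 past the threshold adjusted over the list alone. The call ended without Cre_PD1 replicate 3 (-0.034, limma camera adjusted p = 0.580) and without MKO_PD1 replicate 1 (0.088, adjusted p = 0.212). It also ended with no filter, the filter at 5 TPM, median-of-ratios scaling, quantile normalization and sample quality weights. The same holds for voom, genes of at least 60 reads and the fit without MKO_PD1 replicates 1 and 3. Slc4a1 was at 1.02 ± 0.658 and 4.38 ± 3.31 TPM.

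The fibroblast and stellate cell list (camera adjusted p = 0.262), the extracellular matrix remodelling list (0.805), the epithelial-mesenchymal transition list (0.360), the immediate early and dissociation stress list (0.452) and the adipocyte list (0.519) were not called, with 0 members past the threshold adjusted over the list alone. Among their members, the collagen gene Col6a1 was at 179 ± 67.2 TPM in Cre_PD1 and 57.0 ± 34.6 TPM in MKO_PD1, the pericyte gene Rgs5 at 17.4 ± 2.68 and 25.5 ± 1.47 TPM and Timp2 at 413 ± 26.4 and 195 ± 147 TPM. Vim was at 2963 ± 457 and 1113 ± 753 TPM, Junb at 864 ± 163 and 375 ± 148 TPM and Pparg at 61.9 ± 30.2 and 24.2 ± 10.8 TPM. Without MKO_PD1 replicate 1 the fibroblast list was called higher (0.55, limma camera adjusted p = 0.0107), as it was with the hepatocyte covariate and without MKO_PD1 replicates 1 and 3. In the last fit the extracellular matrix remodelling list was called higher too (limma camera adjusted p = 0.000152). The cholangiocyte list was not called (camera adjusted p = 0.0995) except lower without Cre_PD1 replicate 1 (adjusted p = 0.0367), with the replicate block and with voom, and 3 of its 8 members, Krt19, Spp1 and Sox9, all shared with the liver tumour list, were lower adjusted over the list alone. The oxidative phosphorylation list (camera adjusted p = 0.981) had 12 of 18 members separate and lower, while its median lay 0.19 above that of all genes. Ndufb8 was at 58.2 ± 3.49 and 41.2 ± 6.63 TPM, a log2 difference of -0.50 that median-of-ratios scaling took to about 0. Fry gave this list an unadjusted p of 0.0131 and an adjusted p of 0.236, and camera called it lower with the hepatocyte covariate. Muscle and pancreas markers were low in both groups, with Mylpf at 2.58 ± 0.269 and 3.00 ± 1.25 TPM and Cela1 at 8.58 ± 1.01 and 10.4 ± 1.39 TPM. For the interferon gamma, exhaustion, fibroblast, NK cell, MHC class I and MHC class II lists the median log2 difference was below 0 while camera gave the direction as higher, since the median of all genes was lower still. For the T cell-recruiting chemokine list the median was 0.047 and the mean -0.024.

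Around Trem2 several genes of the same receptor family were higher in MKO_PD1, and none passed the correction. Treml1 (ENSMUSG00000023993.7, chromosome 17, 48359916 to 48367176), which starts 5.77 kb after the end of Trem2 and encodes a receptor of platelet granules, was at 1.11 ± 0.592 TPM in Cre_PD1 and 7.22 ± 2.15 TPM in MKO_PD1 (log2 difference 1.96, SE 0.35, limma adjusted p = 0.168, higher in 3 of 3 MKO_PD1 libraries than in any Cre_PD1 library). It had 13, 30 and 8 reads in Cre_PD1 and 90, 128 and 113 in MKO_PD1. The other genes of this region were chosen after the result for Treml1 was seen. Treml4 was at 9.48 ± 1.70 and 28.0 ± 10.9 TPM (log2 difference 1.41), B430306N03Rik at 5.05 ± 0.807 and 13 ± 2.63 TPM (1.20) and Trem3 at 1.39 ± 0.482 and 4.92 ± 2.94 TPM (1.20), each with limma adjusted p = 0.168. Trem1 overlapped between the groups, at 7.63 ± 1.87 and 10.1 ± 8.35 TPM, as did Treml2, at 1.99 ± 0.101 and 4.40 ± 3.57 TPM. Beyond Treml1, Nfya was at 29.6 ± 4.45 and 17.6 ± 8.27 TPM and Oard1 at 35.2 ± 3.01 and 31.5 ± 1.64 TPM.

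**Figure D3:**
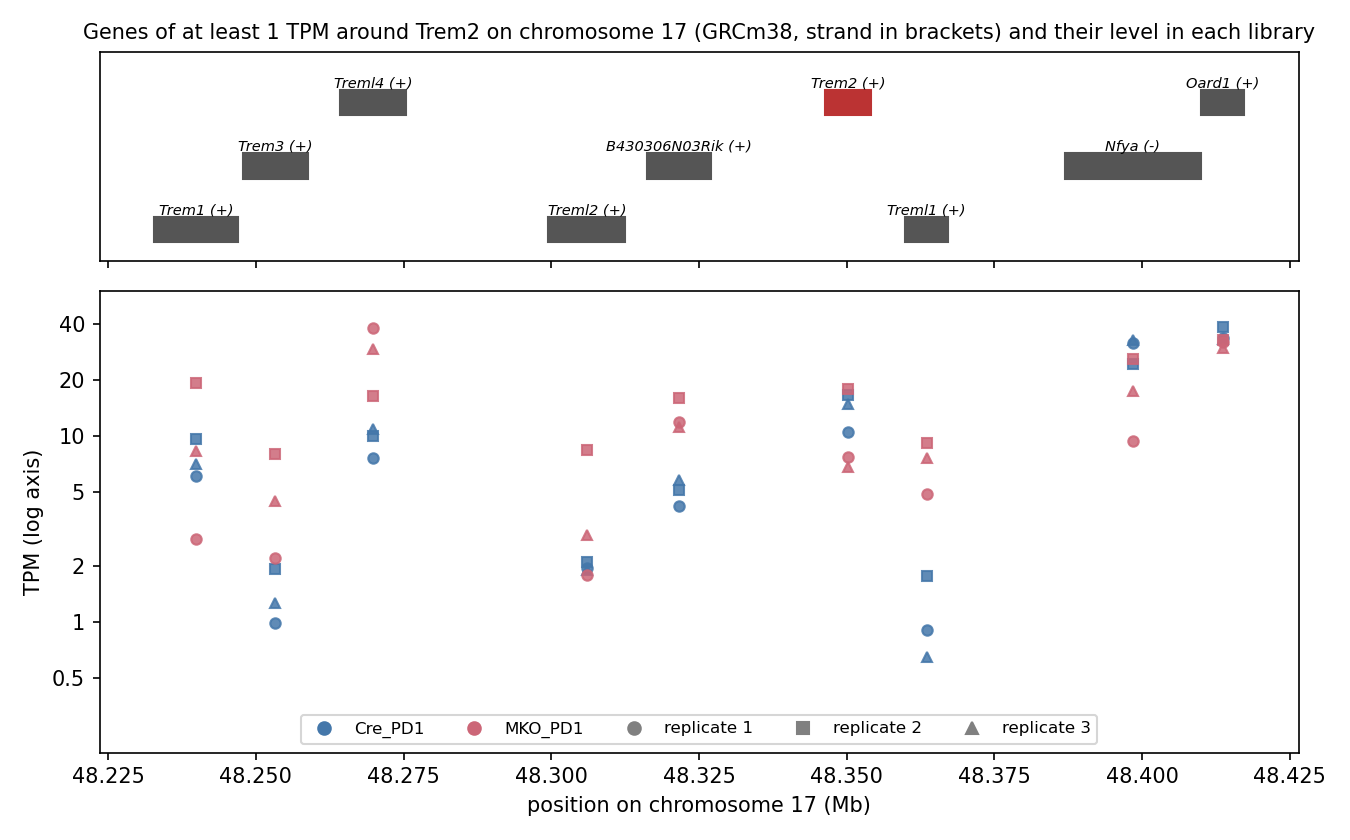
Genes of at least 1 TPM around Trem2 on chromosome 17 of GRCm38 (top, position in Mb) and their level in TPM on a log axis in each library, drawn at the middle of each gene (bottom); colours mark the groups and symbols the replicates. Treml1, 5.77 kb from Trem2, lies at 4.90 to 9.14 TPM in MKO_PD1 and 0.651 to 1.78 TPM in Cre_PD1, and Treml4 is also separate between the groups.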

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

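Chosen after the data were seen were the values as deposited, voom on recovered reads, genes with at least 60 reads, the hepatocyte list mean as a covariate and the fit without MKO_PD1 replicates 1 and 3. The count of 2 genes, Mir7655 and Gm17720, was also found with both other pseudocounts, the hepatocyte list removed, no trend, robust limma and a threshold of 0.1, and was 3 with the values as deposited. In limma it was 0 with no filter (5080 genes at an unadjusted p under 0.05), with the filter at 5 TPM (3752), with quantile normalization (5551), with a block on the replicate number (3279), with voom (4724), with genes of at least 60 reads (4422) and with the hepatocyte covariate (396). It was 1, Mir7655, with median-of-ratios scaling. Without MKO_PD1 replicates 1 and 3 it was 1, a gene other than these 2, in a fit that assumes the lone MKO_PD1 library varies like the other group. Leaving out 1 library at a time gave 0 to 7314 genes, the highest without MKO_PD1 replicate 2. Sample quality weights gave 10551 genes, 2330 higher and 8221 lower, with weights from 0.190 to 11, the highest on MKO_PD1 replicate 3. The default way of estimating them did not converge (1 weight of 498000, 12056 genes), so these counts rest on how the weights are estimated. Depth limits both genes, since Mir7655 and Gm17720 have 16 and 7 reads and the filter at 60 reads removes them.

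The difference in Trem2 went from -0.44 to -0.96 with sample quality weights (limma adjusted p = 0.00347, the lowest in a range up to 1.0) and from -0.84 to -0.20 with each library left out. The median of all genes was -0.40 with these weights and -0.66 without MKO_PD1 replicate 2, the fit that gave -0.84 for Trem2. The Trem2 difference changed sign to 0.018 with median-of-ratios scaling, to 0.024 with voom and to 0.36 without MKO_PD1 replicates 1 and 3. The first 2 remove the shift of the all-gene median. The third leaves MKO_PD1 replicate 2 alone in its group, with the highest Trem2 level of the 6 libraries (18.0 TPM). The number of lists called was 0 with an estimated correlation and 0 with fry, 15 to 24 with each library left out, and 16 to 25 in the other alternatives.

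Lists that changed direction are given as median minus the all-gene median, while the direction is that of camera, so a list may test as lower with a value above 0. With the hepatocyte covariate these were Kupffer cell (-0.14), cholesterol and fatty acid synthesis (0.0056), hepatocyte (0.041, a list that is then its own covariate) and regulatory T cell (0.52, called higher). With sample quality weights they were T cell (-0.0044) and cytotoxic effector (0.049), and with each library left out the T cell list ran from 0.054 to 0.71 and the cytotoxic list from -0.046 to 0.78, lowest without MKO_PD1 replicate 2. Without MKO_PD1 replicates 1 and 3 they were cholesterol and fatty acid synthesis (0.084), extracellular matrix remodelling (0.78) and regulatory T cell (0.65), the last 2 called higher. Apart from the covariate's own list the cause was not tested. Over 858 alternatives of 36 lists, 724 kept side and direction, 103 lost a call, 20 gained one and 11 changed direction. Over 3388 alternatives of the 158 genes of the naming rule other than Trem2 the numbers were 3144, 8, 236 and 0. Among those counted as kept, 41 list and 99 gene differences that were never past the threshold changed sign. The replicate numbers gave no sign of pairing: deviations from the group means correlated at -0.42, -0.26 and 0.049 between libraries of the same number, across genes. With 3 libraries per group and 71.9% of the variance on the first principal component, these correlations cannot exclude a pairing.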

Other observations

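The acute phase, pericentral, periportal, eosinophil, mast cell and basophil, liver-resident, recruited macrophage and Y-linked tests and the tests of T cell against tumour genes, of depth, of a few abundant genes and of macrophage RNA were chosen after the result was seen. The platelet list was chosen after the rise of Treml1 was seen, and its bound was set before the platelet values were. The splits were set before their result. Acute phase genes, which hepatocytes secrete in inflammation, were higher in MKO_PD1, with 10 of 12 separate between the groups and a median log2 difference of 1.92 (camera adjusted p = 1.49e-12; adjusted p = 0.161 with an estimated correlation). The serum amyloid gene Saa1 was at 525 ± 338 TPM in Cre_PD1 and 2865 ± 2310 TPM in MKO_PD1, and the pentraxin gene Apcs at 193 ± 15.9 and 1315 ± 913 TPM. Against the hepatocyte list mean, however, the acute phase mean overlapped between the groups, at -0.24, -1.05 and -1.79 in Cre_PD1 replicates 1, 2 and 3 and -0.79, -1.14 and -0.77 in MKO_PD1 replicates 1, 2 and 3. Genes of hepatocytes around the central vein and around the portal vein, 10 each with 2 and 1 in other lists, were both higher, with medians of 1.52 (camera adjusted p = 1.69e-07; adjusted p = 0.172 with an estimated correlation) and 1.45 (camera adjusted p = 1.82e-09; adjusted p = 0.161 with an estimated correlation). Cyp2c50, of the first zone, was at 75.2 ± 54.5 and 245 ± 110 TPM and Hal, of the second, at 13.2 ± 9.51 and 51.5 ± 30.2 TPM.

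Eosinophil genes had a median log2 difference of 1.04 (camera adjusted p = 0.00501; adjusted p = 0.161 with an estimated correlation), and 3 of 5 were separate and higher: Prg2 at 2.12 ± 0.936 and 6.87 ± 2.54 TPM, Ccr3 at 0.436 ± 0.0851 and 2.07 ± 1.11 TPM and Ear2 at 19.2 ± 5.51 and 57.6 ± 30.7 TPM. Il5ra, the interleukin 5 receptor gene, was lower, at 64.4 ± 36.7 and 14.2 ± 10.8 TPM. Of 7 mast cell and basophil genes only Prss34 was separate, with a list median of 0.35 (camera adjusted p = 0.00414; adjusted p = 0.323 with an estimated correlation). Klra4, an NK cell receptor gene, was at 114 ± 41.6 TPM in Cre_PD1 and 36 ± 24.3 TPM in MKO_PD1, whereas the NK cell gene Ncr1 was at 0.886 ± 0.824 and 1.40 ± 0.126 TPM. The T cell list mean minus that of the liver tumour list was -3.92, -3.47 and -3.30 in Cre_PD1 replicates 1, 2 and 3. In MKO_PD1 replicates 1, 2 and 3 it was -2.13, -1.72 and -2.78, which separates the groups, although the T cell list itself overlapped. The liver tumour list alone separated them already, at most 6.46 in MKO_PD1 and at least 6.84 in Cre_PD1. The T cell mean was below every Cre_PD1 library in MKO_PD1 replicates 1 and 3 (2.51 and 2.95) and above every one in replicate 2 (4.75). The separation thus does not show more T cell RNA in MKO_PD1. Minus the hepatocyte list mean the T cell mean overlapped too, at -5.23, -6.38 and -6.16 in Cre_PD1 and -9.16, -5.32 and -8.31 in MKO_PD1.

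With the preset correlation hepatocyte genes were called higher and tumour and cell cycle genes lower in MKO_PD1, calls that were lost with an estimated correlation (camera adjusted p = 0.668, 0.830 and 0.830). The tables argue against depth, since the deepest MKO_PD1 library, with 32.9 M reads, lies inside the range of Cre_PD1, and against a few abundant genes, since after median-of-ratios scaling the highest cell cycle mean of MKO_PD1 minus the lowest of Cre_PD1 was still -0.18 (Cre_PD1 SD 0.081). More non-tumour liver in the RNA of MKO_PD1 tumours may account for the pattern. A set of 15 genes of liver sinusoidal, Kupffer and stellate cells, 6 of them in other lists, had a median log2 difference of 1.0 (SE 0.23). This SE, like those of the medians below, was taken over genes, which are not independent replicates. It does not measure the spread between tumours. The medians were 1.65, 0.29 and 1.28 in MKO_PD1 replicates 1, 2 and 3, and no sort was used that would remove such cells. For 4 of 4 gene pairs the ratio of the Y-linked to the X-linked gene was above every Cre_PD1 library in all MKO_PD1 libraries, by 1.88 (Ddx3y and Ddx3x) to 2.10 (Eif2s3y and Eif2s3x), which is consistent with more host RNA against tumour cells low in Y-linked expression, though the sex of the mice is not given. With the hepatocyte list mean as a covariate the liver tumour list kept its lower call, while the cell cycle list lost it. That fit separates group from hepatocyte share poorly. In MKO_PD1 replicate 2, with a hepatocyte share of 5.04%, the liver tumour list mean (6.46) lay below the Cre_PD1 range of 6.84 to 6.93. That replicate also had the highest T cell (4.75), pan-macrophage (6.59), neutrophil (5.70) and fibroblast and stellate cell (6.16) list means of the 6 libraries. Hepatocyte share alone thus need not account for the whole pattern, and the part of other host cells in it was not tested. What stays open is whether the sampled pieces held more liver or other host cells or the genotype left less tumour in them. The labels give no tumour size or histology.

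Trem2 was lower against the pan-macrophage list mean in MKO_PD1 (exact permutation p = 0.1). A larger part of Kupffer cells, which could carry little Trem2, among the macrophages and the knockout itself cannot be told apart here. In MKO_PD1 replicate 2 the Kupffer cell list mean (5.93) lay inside the Cre_PD1 range of 5.07 to 5.93. The pan-macrophage mean (6.59) lay above its Cre_PD1 range of 5.31 to 5.59, and the Trem2 ratio was -2.40. This runs against a larger part of Kupffer cells there, but 1 library does not exclude it. The test was on 10 genes of recruited tumour macrophages, 5 of them in other lists. Against the pan-macrophage list their median log2 change was -0.35 (SE 0.38 over genes), beside a bound of -0.43. Of these genes 4 fell by more than Trem2, so the spread spans the bound. As a list they were not called (median 0.032, camera adjusted p = 0.183, or 0.668 with an estimated correlation). The knockout is the biological explanation the design names and is untested, since the deleted exons are not given. A changed share of other myeloid cells was not tested for this ratio either. Neutrophil and monocyte list means lay above every Cre_PD1 library in MKO_PD1 replicates 2 (5.70 and 6.38) and 3 (4.37 and 5.39). In replicate 1 (3.63 and 4.66) they did not.

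Treml1 was higher in MKO_PD1, short of the correction (limma adjusted p = 0.168). Platelets or megakaryocytes as its source stay open. For 11 platelet genes, none of them in another list, the median log2 difference was 0.58 (SE 0.28 over genes), below the bound of 0.98 by more than that SE. Camera gave them an adjusted p = 0.000117, or 0.182 with an estimated correlation. The members went both ways, so the median does not decide. Ppbp (1.47, at 10.5 ± 5.09 and 29.9 ± 12.5 TPM), Clec1b (1.57) and Gp9 (1.21) passed the bound. These and Gp5 (0.86) were separate and higher, while Itgb3 (-0.84) and Gp1ba (-0.45) were lower. More macrophage RNA is argued against, since the lowest MKO_PD1 ratio of Treml1 to the pan-macrophage list lay 0.76 above the highest of Cre_PD1, with an SD of 0.42. An effect of the edited Trem2 allele on the neighbouring gene could be a further source and stays open, as the labels do not describe the allele.

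With 3 against 3 samples there are 10 splits, too few for a share under 0.05. For genes changed the real split gave 2 and the highest other split 0, so 1 of 10 splits gave as many. For gene lists called the real split gave 22 and the others from 10 to 23, so 2 of 10 gave as many. The liver-resident list had 4 genes separate and higher and 1 lower (camera adjusted p = 5.47e-08; adjusted p = 0.161 with an estimated correlation).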
